A study of Homo sapiens with 12 samples.

How the data were processed

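RNA was measured in 12 libraries of enterocytes differentiated from the human induced pluripotent stem cell line RPChiPS771. The groups were Control, VD3 (1 µM), VPA (100 µM) and VD3VPA (both), with 3 libraries each, treated from day 15 to day 23. The libraries were poly-A selected and prepared from 1 µg of RNA with a NEBNext Ultra kit, per the labels. The submitters' processing notes name HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 1.20.0 and the build GRCh38.p13, and the role of each tool and the strand setting of the counting are not given in the sources used here.

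The deposited file holds FPKM values per gene and library and the length of each gene, per the file headers. Its 58735 genes match GENCODE release 29 in identifier, start and end, 58735 of them each. Multiplying each FPKM by the gene length and a constant of its library gave whole fragment numbers for 100% of values, within 0.01, and these recovered fragments were used for counting errors and checks only. The scaling in the deposited FPKM values equals median-of-ratios size factors of the recovered fragments. All measured columns were mapped to libraries. The 518 genes of chromosome Y and XIST were left out of every step. A total of 175 symbols are used by more than 1 gene, so genes were handled by identifier.

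The main analysis used log2(FPKM + 1) values of genes with at least 1 FPKM in at least 3 libraries, 12561 genes. A linear model with a mean per group was fitted in limma 3.58.1 with a trended prior (R 4.3.3, statmod 1.5.0 and version 1.17.8 of the data.table package), with 8 residual degrees of freedom and 3.28 from the prior. It gave 8 comparisons: the 5 pairs named in the report, the interaction, and the average effect of each compound. P-values were adjusted with the Benjamini-Hochberg method within each comparison, and an adjusted p under 0.05 counted as called. Changes of at least 2-fold were counted among the called genes. Figures and preparation used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9. The median SE of a log2 fold change was 0.0658 for a pair of groups, 0.0931 for the interaction and 0.0466 for the averages. Fold ratios are ratios of group mean FPKM, and a gene with 1 to 3 fragments in a group has an exact counting interval of 95% in their place, which CYP3A4 has as well.

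A total of 28 gene lists with 647 genes were written before the data were examined, and 25 with at least 5 tested genes were tested with camera in limma with a preset correlation of 0.01. The same test was run with the correlation estimated from the residuals, and with fry. The estimated correlation called 0 of 200 list results (15 had an unadjusted p under 0.05, lowest adjusted p 0.114), and fry called 137. The fit, the threshold, the lists, most of the other settings tried and the rule for named genes were all chosen before the data were examined. The rule named the 10 largest rises and 10 largest falls among called protein-coding genes for VD3, VPA and VD3VPA against Control, and 5 of each for the other comparisons. For pairs of groups and averages, all libraries of one side had to lie beyond those of the other. It also named 14 fixed genes and up to 3 genes with the smallest adjusted p in each list, and the last are given only for lists the text describes.

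The fit was tested on simulated counts with known changes in 50 genes at each size and a dispersion of 0.00353. For VD3 against Control it recovered 34%, 82%, 92% and 88% of genes changed 1.25-fold, 1.5-fold, 2-fold and 4-fold, and called 0.0338% of unchanged genes. For VPA against Control it recovered 42%, 86%, 92% and 96%, and called 0.0254%. In the real data 62.5% of genes were called with VD3 and 52.7% with VPA. With far fewer changed genes the adjusted threshold is stricter in the simulation, which also gave all genes 1 dispersion. These shares therefore do not measure the recovery or the false calls in the real data. Other settings chosen in advance changed the pseudocount, the filter, the scaling (equal FPKM sums, median-of-ratios, quantile), the prior, library weights, the groups fitted, the gene class and the fold threshold, added a replicate block, or left out each library in turn. Settings chosen after seeing the data were voom on recovered fragments, scaling to each library's own total, and removal of trends on GC content (known for 12556 tested genes) and gene length, with and without the replicate block. Lists under other scalings, and the agreement between effects under median-of-ratios scaling, were also added after seeing the data. A test on deposited counts was not run, as the table used holds FPKM.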

Results

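Gene expression was measured by RNA sequencing in enterocytes, the absorptive cells of the intestinal lining, differentiated from the human induced pluripotent stem cell line RPChiPS771. Each library pooled the RNA of many cells, so a shift in the mix of cell types cannot be told apart from a change within enterocytes. The cultures received neither compound (Control), 1 µM vitamin D3 (VD3), 100 µM valproic acid (VPA) or both compounds (VD3VPA). Treatment ran from day 15 to day 23, the maturation stage of the protocol. VPA is an inhibitor of histone deacetylases, the enzymes that remove acetyl groups from histones. VD3 is known to act through the vitamin D receptor once it has been converted to its active hormone, and the form used was not given in the sources used here. Each of the 4 groups had 3 libraries, 12 in all, and the stated purpose was to learn how VPA and VD3 affect differentiation and the expression profile. The libraries held 32160289 to 43998467 fragments assigned to genes, as recovered from the deposited values. Group levels below are mean FPKM (fragments per kilobase of gene, scaled to library size) ± SD over 3 libraries. Log2 fold changes, with their standard error (SE), are on the log2(FPKM + 1) scale, which understates the change of genes at low levels. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

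The 12 libraries fell into their 4 groups on the leading principal components of the 12561 genes tested. The component with 63.8% of the variance separated the 6 libraries with VD3 from the 6 without it. The next component, with 18.1%, separated VPA from Control most widely, with VD3 and VD3VPA between them. Replicate libraries differed by more than sampling noise in every pair, with a chi-square per gene of 3.4 to 17, so no pair was treated as copies of a single library.

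**Figure D1:**
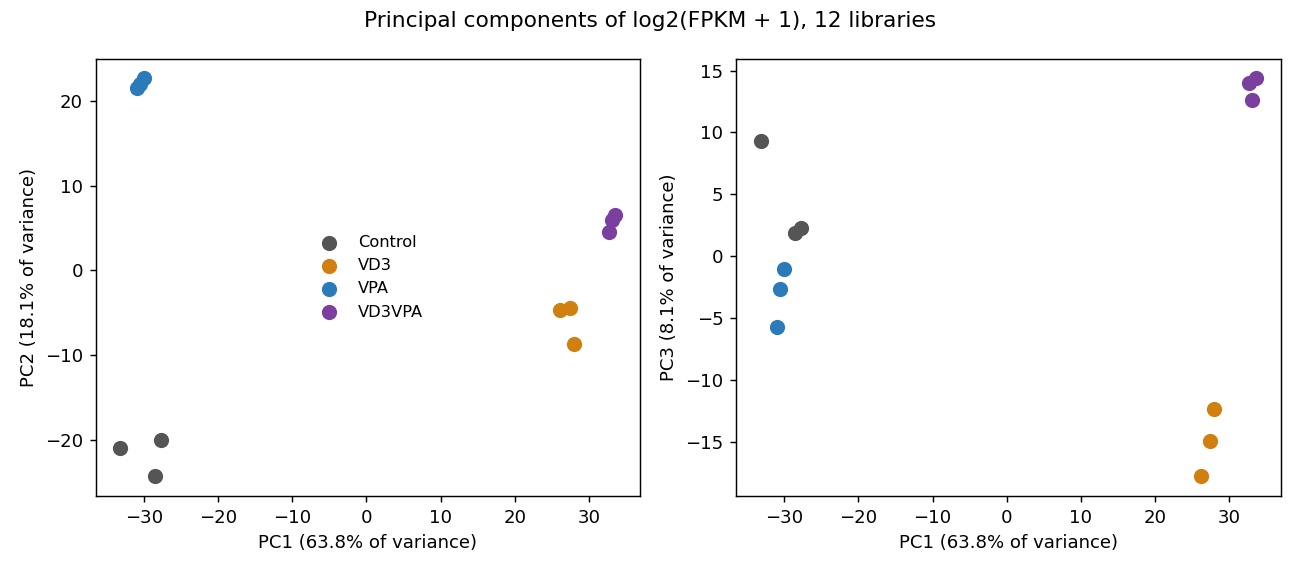
Principal component scores of the 12 libraries from log2(FPKM + 1) values, with component 1 (63.8% of the variance) on both horizontal axes and components 2 (18.1%) and 3 (8.07%) on the vertical axes. Each point is a library, coloured by group, and the libraries with VD3 lie on the right of component 1.

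The comparison of VD3 with Control addressed what VD3 does alone at this stage. The 10 largest rises included S100G, CYP24A1, TRPV6 and CYP3A4. S100G, an intestinal calcium-binding protein (chromosome X, 16650158 to 16654670 in GRCh38), stood at 0.395 ± 0.201 FPKM in Control and 1535 ± 172 with VD3 (n = 3 each). CYP24A1, the enzyme that inactivates the vitamin D hormone (chromosome 20, 54153449 to 54173973), rose from 1 fragment in all Control libraries together to 384289 fragments. That is a ratio of 456000, with a 95% counting interval of 81800 to 1.8e+07, and a level of 928 ± 76.0 FPKM with VD3. The apical calcium channel TRPV6 (chromosome 7, 142871203 to 142885762) rose 885-fold, to 33.3 ± 0.226 FPKM. CYP3A4, a main drug-oxidizing enzyme of intestine and liver (chromosome 7, 99756960 to 99784265), rose 858-fold, to 23.6 ± 1.72 FPKM. It had 10 fragments in the Control libraries together, so its ratio has a 95% counting interval of 496 to 1900, and the ratio was 1343 without Control replicate 1.

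Lactase (LCT) of the brush border went from 4.64 ± 0.579 to 93.3 ± 3.30 FPKM and intestinal alkaline phosphatase (ALPI) from 9.87 ± 0.346 to 218 ± 12.3 FPKM, 20.1-fold and 22.1-fold. The other genes among the 10 largest rises were CP, which encodes the copper-carrying ferroxidase ceruloplasmin (35.3 ± 2.46 FPKM with VD3), C6orf15 (64.5 ± 7.79), PRODH2 of hydroxyproline breakdown (20.8 ± 3.72) and the cytokine receptor gene CSF3R (70.4 ± 6.58). Among the largest falls, TDO2 of tryptophan breakdown dropped from 25.2 ± 2 to 2.63 ± 0.530 FPKM, and the growth-promoting transcription factor MYC from 11.6 ± 1.24 to 1.80 ± 0.638. The mitochondrial chaperone HSPD1 dropped from 157 ± 17.2 to 42.0 ± 1.28 FPKM. NPW, AKR1B10, AGR3, RPL22L1, SMTNL2 and FABP5 fell by 2.58, 2.26, 2.24, 2.21, 2.05 and 2.02 on the log2 scale. BOLA2B also met the rule for large falls, but its fragments cannot be separated with certainty from its near-identical copy BOLA2 and its Control level varied widely (20.3 ± 16.6 FPKM), so it is reported as uncertain.

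In all, 3930 genes rose and 3922 fell with VD3 at an adjusted p under 0.05 (limma with Benjamini-Hochberg adjustment), and 4709 did not pass. A change of at least 2-fold was found for 804 of them, 472 higher and 332 lower. The share of higher genes among the calls was 50.1%, but 40.4% with libraries scaled to their own totals, 44.3% scaled to equal FPKM sums and 45.9% with GC content and length trends removed, so this balance depends on the scaling. The adjusted p was 9.1e-08 for S100G (log2 fold change 10.11, SE 0.603), 2.97e-11 for CYP24A1 (9.85, SE 0.203), 1.51e-12 for CYP3A4 (4.58, SE 0.060) and 2.09e-11 for TRPV6 (5.05, SE 0.099). CYP3A4 has closely related family members, so fragments shared between them leave its exact level uncertain.

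Vitamin D receptor target genes rose as a group: 20 of the 23 tested rose, 1 fell and 2 did not pass, with 20 and 1 adjusted over the list alone (camera adjusted p = 7.31e-08; adjusted p = 0.252 with an estimated correlation). CYP24A1, CYP3A4 and TRPV6 had the smallest adjusted p in the list. Of 21 tested genes of tight and adherens junctions, which seal neighbouring epithelial cells, 13 rose, 2 fell and 6 did not pass. The counts adjusted over the list alone were also 13 and 2 (camera adjusted p = 0.00604; adjusted p = 0.453 with an estimated correlation). CLDN2, a claudin that forms cation pores, went from 2.57 ± 0.693 to 47.9 ± 3.6 FPKM, while F11R and CLDN7 rose by 0.63 and 0.44 on the log2 scale. Proliferation genes fell: 0 of 15 rose, 14 fell and 1 did not pass, and 14 fell adjusted over the list alone (camera adjusted p = 2.26e-05; adjusted p = 0.449 with an estimated correlation). The replication factor MCM7 dropped from 5.73 ± 0.479 to 2.76 ± 0.109 FPKM and RRM2, a subunit of ribonucleotide reductase, from 1.82 ± 0.380 to 0.144 ± 0.0549.

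Of 20 genes listed as responsive to histone deacetylase inhibitors, 14 rose with VD3 alone, 1 fell and 5 did not pass, and 14 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.000526; adjusted p = 0.449 with an estimated correlation). TP53INP1, CLU and HPGD led it, at 1.55, 1.05 and 1.2 on the log2 scale. In the list of p53 target genes, which also holds TP53INP1, 15 of 20 rose, 1 fell and 4 did not pass, with 15 and 1 adjusted over the list alone (camera adjusted p = 0.00604; adjusted p = 0.453 with an estimated correlation). Of 25 genes of cholesterol synthesis, 16 rose, 2 fell and 7 did not pass, with 16 and 2 adjusted over the list alone. Its camera adjusted p was 0.0264 (adjusted p = 0.691 with an estimated correlation) and reached 0.0839 without VD3 replicate 3. Its range was 0.0123 to 0.0839 over all alternatives other than the estimated correlation and fry. MSMO1 of the pathway rose by 0.89 on the log2 scale.

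The remaining lists did not pass the set test with VD3. Many of their members changed, but so did 62.5% of all genes tested, and these counts alone do not set the lists apart. Phase I drug-metabolizing enzymes had 13 genes higher, 6 lower and 4 not past of 23, and 22 changed adjusted over the list alone (camera adjusted p = 0.0872). Within it CYP3A5 went from 6.60 ± 0.178 to 86.4 ± 4.70 FPKM and the retinal-oxidizing ALDH1A1 from 30.3 ± 1.74 to 7.87 ± 0.518. Phase II conjugating enzymes had 7 higher, 12 lower and 4 not past of 23 (19 changed adjusted over the list alone; camera adjusted p = 0.27), with UGT1A1, which conjugates bilirubin, at 3.80 ± 0.0284 in Control and 34.2 ± 6.92 FPKM with VD3. Intestinal transporters had 12 higher, 9 lower and 6 not past of 27 (22 adjusted over the list alone; camera adjusted p = 0.854), and the list's median of -0.11 and mean of 0.04 differ in sign. The folate carrier SLC46A1 went from 8.32 ± 0.302 to 26.8 ± 0.594 FPKM and the iron exporter SLC40A1 from 32.2 ± 2.22 to 14.8 ± 0.680. Brush border and enterocyte markers had 12 higher, 9 lower and 7 not past of 28 (21 adjusted over the list alone; camera adjusted p = 0.27). Lipid absorption genes had 13 higher, 7 lower and 6 not past of 26 (21 adjusted over the list alone; camera adjusted p = 0.182).

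Transcription factors and nuclear receptors of the intestine had 13 genes higher, 7 lower and 8 not past of 28 (20 adjusted over the list alone; camera adjusted p = 0.27), led by the aryl hydrocarbon receptor AHR at 1.22 on the log2 scale. Histone deacetylases and sirtuins had 7 higher, 0 lower and 8 not past of 15 (7 adjusted over the list alone; camera adjusted p = 0.185). Fatty acid oxidation genes had 9 higher, 8 lower and 8 not past of 25 (17 adjusted over the list alone; camera adjusted p = 0.873). The integrated stress list had 6 higher, 7 lower and 7 not past of 20 (13 adjusted over the list alone; camera adjusted p = 0.926), with a median below 0 and a mean above it. Metal handling genes had 5 higher, 3 lower and 8 not past of 16 (8 adjusted over the list alone; camera adjusted p = 0.621). Among these the manganese exporter SLC30A10 went from 3.97 ± 0.384 to 50.8 ± 3.30 FPKM and the ferritin chain FTH1 from 358 ± 22.7 to 1442 ± 178. Interferon-stimulated genes had 5 higher, 2 lower and 1 not past of 8 (7 adjusted over the list alone; camera adjusted p = 0.27). BMP, TGF beta and Notch responsive genes had 7 higher, 6 lower and 2 not past of 15 (13 adjusted over the list alone; camera adjusted p = 0.854), with the Notch ligand JAG1 at 18.9 ± 0.703 in Control and 6.86 ± 0.908 FPKM with VD3.

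Markers of other cell types moved in both directions with VD3. Hepatocyte markers had 11 genes higher, 4 lower and 4 not past of 19 (15 adjusted over the list alone; camera adjusted p = 0.141). The fibrinogen chain genes FGB and FGA stood at 633 ± 76.6 and 226 ± 20.5 FPKM in Control and at 3371 ± 194 and 1569 ± 168 with VD3. Intestinal stem cell markers had 5 higher, 5 lower and 2 not past of 12 (10 adjusted over the list alone; camera adjusted p = 0.873). Goblet and Paneth cell markers had 3 higher, 3 lower and 0 not past of 6 (6 adjusted over the list alone; camera adjusted p = 0.873), and enteroendocrine markers 1 higher, 4 lower and 0 not past of 5 (5 adjusted over the list alone; camera adjusted p = 0.557). Tuft and microfold cell markers had 1 higher, 3 lower and 1 not past of 5 (5 adjusted over the list alone; camera adjusted p = 0.117). Mesenchymal markers had 5 higher, 0 lower and 5 not past of 10 (5 adjusted over the list alone; camera adjusted p = 0.116), led by SPARC at 1.60 on the log2 scale. Pluripotent cell markers had 1 higher, 4 lower and 1 not past of 6 (5 adjusted over the list alone; camera adjusted p = 0.246). Gastric markers had 3 genes tested, 0 higher, 2 lower and 1 not past (2 adjusted over the list alone). Neural markers had 2 tested, 1 higher and 1 not past (2 adjusted over the list alone), and endothelial, blood and muscle markers 3 tested, 2 higher and 1 not past (2 adjusted over the list alone). These last 3 lists were too short for the set test.

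The comparison of VPA with Control addressed the effect of VPA alone. The largest rises were in HSD3B1, a steroid-forming dehydrogenase (chromosome 1, 119507198 to 119515054), at 2.49 ± 0.510 FPKM in Control and 29.8 ± 0.882 with VPA, and ALPL, the alkaline phosphatase of bone and liver, at 0.339 ± 0.127 and 9.01 ± 0.804 (n = 3 each). MSX1, a homeobox transcription factor, rose 6.30-fold, the sulfotransferase SULT2A1 5.21-fold, the bile acid carrier SLC10A1 5.32-fold, GNRH2 5.52-fold and CNN3 6.23-fold. MYL3 and PTH1R rose 7.07-fold and 5.96-fold, but their annotations overlap (chromosome 3, 46857872 to 46882169 and 46877746 to 46903799), so reads from them may be shared and both are uncertain. AGR2, an endoplasmic reticulum protein of mucus-secreting cells (chromosome 7, 16791811 to 16833433), fell from 153 ± 50 to 18.6 ± 1.09 FPKM. TFF1 of the gastric mucosa fell from 85.5 ± 10.2 to 15.6 ± 2.26, and ODC1, which starts polyamine synthesis, from 431 ± 79.2 to 92.5 ± 14.9.

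The other large falls were in NPW, AKR1B10, ATP6V0D2, ANXA13 and FGG, by 2.55, 2.44, 2.06, 1.93 and 1.85 on the log2 scale. UGT2B15 fell by 2.35 and belongs to a family of near-identical genes, which leaves its level uncertain, as does the wide Control spread of BOLA2B. With VPA, 3715 genes rose and 2899 fell at an adjusted p under 0.05 (limma with Benjamini-Hochberg adjustment), and 5947 did not pass. A change of at least 2-fold was found for 363 genes, 267 higher and 96 lower. The adjusted p was 2.14e-08 for HSD3B1 (3.15, SE 0.113), 3.48e-08 for ALPL (2.90, SE 0.118) and 2.56e-07 for AGR2 (-2.93, SE 0.168). The share of higher genes among the calls was 56.2%, but 43.8% with libraries scaled to equal FPKM sums, 36.3% scaled to their own totals and 45.8% with GC content and length trends removed. The balance of small rises and falls with VPA therefore depends on the scaling.

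Genes of lipid absorption and lipoprotein assembly rose as a group with VPA: 17 of 26 rose, 1 fell and 8 did not pass, with 17 and 1 adjusted over the list alone (camera adjusted p = 4.9e-05; adjusted p = 0.329 with an estimated correlation). APOB, the structural protein of chylomicrons, went from 437 ± 17.4 to 877 ± 44.3 FPKM, the lipid droplet protein PLIN2 from 11.9 ± 1.49 to 41.6 ± 1.56 and the transcription factor CREB3L3 from 20.5 ± 0.982 to 86.0 ± 5.13. APOA4, an apolipoprotein of chylomicrons and among the 10 largest rises, increased 5.2-fold. Intestinal transporters rose: 19 of 27 were higher, 2 lower and 6 not past, with 19 and 2 adjusted over the list alone (camera adjusted p = 8.82e-05; adjusted p = 0.114 with an estimated correlation). SLC40A1 went from 32.2 ± 2.22 to 68.2 ± 4.15 FPKM and SLC46A1 from 8.32 ± 0.302 to 18.0 ± 0.675. Of 25 genes of fatty acid oxidation, 17 rose, 3 fell and 5 did not pass, and 18 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.00698; adjusted p = 0.487 with an estimated correlation). PDK4, a kinase that restrains pyruvate oxidation, went from 0.0809 ± 0.0477 to 4.08 ± 1.09 FPKM.

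BMP, TGF beta and Notch responsive genes had 9 higher, 0 lower and 6 not past of 15, with 9 adjusted over the list alone (camera adjusted p = 0.00565; adjusted p = 0.437 with an estimated correlation), among them SMAD6, ID2 and ID3 at 0.80, 0.62 and 0.60 on the log2 scale. Proliferation genes fell with VPA too: 0 rose, 13 fell and 2 did not pass of 15, with 13 adjusted over the list alone (camera adjusted p = 8.27e-06; adjusted p = 0.329 with an estimated correlation). MCM7 went from 5.73 ± 0.479 to 2.19 ± 0.125 FPKM, and MCM3 and MCM4 fell by 0.83 and 0.98 on the log2 scale. Genes of the integrated stress and unfolded protein response had 3 higher, 11 lower and 6 not past of 20, with 3 and 11 adjusted over the list alone (camera adjusted p = 0.0111; adjusted p = 0.487 with an estimated correlation). PSAT1 of serine synthesis and CHAC1 of glutathione breakdown each fell by 0.71 on the log2 scale, while DDIT4 rose by 0.70.

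Genes listed as responsive to histone deacetylase inhibitors did not pass the set test with VPA: 9 rose, 4 fell and 7 did not pass of 20, with 9 and 4 adjusted over the list alone (camera adjusted p = 0.485). In this list the linker histone gene H1F0 rose from 102 ± 6.39 to 148 ± 2.78 FPKM and TXNIP fell from 28.3 ± 4.20 to 7.99 ± 0.411. Vitamin D receptor targets had 11 higher, 3 lower and 9 not past of 23, and 13 and 3 adjusted over the list alone (camera adjusted p = 0.183). The sirtuin and deacetylase genes SIRT2 and HDAC11 rose by 0.59 and 0.60 on the log2 scale and HDAC7 fell by 0.32, in a list with 3 higher, 2 lower and 10 not past of 15 (5 adjusted over the list alone; camera adjusted p = 0.864). Brush border and enterocyte markers had 13 higher, 6 lower and 9 not past of 28 (19 adjusted over the list alone; camera adjusted p = 0.183), with the aminopeptidase ENPEP at 1.44 ± 0.223 in Control and 9.16 ± 0.891 FPKM with VPA. Hepatocyte markers had 3 higher, 10 lower and 6 not past of 19 (14 adjusted over the list alone; camera adjusted p = 0.0856), and FGG went from 201 ± 17.7 to 56.9 ± 17.2 FPKM. Mesenchymal markers had 3 higher, 1 lower and 6 not past of 10 (3 adjusted over the list alone; camera adjusted p = 0.527), with a median of -0.12 and a mean of 0.30 on the log2 scale.

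The comparison of VD3VPA with Control gave the joint effect of the compounds. CYP3A4 reached 61.5 ± 3.27 FPKM against 0.0274 ± 0.0173 in Control, and S100G, CYP24A1 and TRPV6 reached 2069 ± 210, 1427 ± 85.3 and 46.0 ± 0.135 FPKM. LCT and ALPI stood at 152 ± 6 and 314 ± 22.6 FPKM, 32.6-fold and 31.8-fold above Control. PRG4, which encodes the lubricating glycoprotein lubricin (chromosome 1, 186296279 to 186314562), rose from 0.0617 ± 0.0225 to 28.3 ± 4.03 FPKM. The other rises of the rule were CP at 59.8 ± 4.96, PRODH2 at 50.5 ± 5.02 and CSF3R at 88.9 ± 2.18 FPKM. TDO2, MYC, NPW and AGR3 fell by 3.14, 2.84, 2.69 and 2.64 on the log2 scale. UGT2B15 (uncertain as above), AKR1B10, AGR2, BTNL3, DKK4 and ERVMER34-1 fell by 2.54, 2.53, 2.49, 2.41, 2.30 and 2.28.

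With both compounds 3909 genes rose and 4163 fell at an adjusted p under 0.05 (limma with Benjamini-Hochberg adjustment), and 4489 did not pass. A change of at least 2-fold was found for 956 genes, 609 higher and 347 lower. The share of higher genes among the calls was 48.4%, and 43.8% with libraries scaled to their own totals. The adjusted p was 8.49e-14 for CYP3A4 (5.93, SE 0.060) and 8.23e-12 for PRG4 (4.78, SE 0.087). Vitamin D receptor targets had 19 higher, 0 lower and 4 not past of 23, with 19 adjusted over the list alone (camera adjusted p = 1.4e-07; adjusted p = 0.276 with an estimated correlation). Tuft and microfold cell markers had 0 higher, 4 lower and 1 not past of 5, with 4 lower adjusted over the list alone (camera adjusted p = 0.0454; adjusted p = 0.321 with an estimated correlation). This list had too few tested genes for the set test without any of the Control libraries or VPA replicate 2, so its call was not tested there. TNFRSF11B, a decoy receptor found on microfold cells, and SPIB, their transcription factor, fell by 2.05 and 0.69 on the log2 scale.

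Other lists passed the set test for VD3VPA against Control with calls that were lost without single libraries. The filter on low values was applied anew without each library, so members of a list could drop out with it. Proliferation genes had 1 higher, 12 lower and 2 not past of 15, and 1 and 13 adjusted over the list alone (camera adjusted p = 0.0035; adjusted p = 0.603 with an estimated correlation). That p was 0.0953 without Control replicate 1 and 0.0561 without Control replicate 2, while the median log2 fold change went from -0.58 to -0.66 and -0.71. Its range was 0.00322 to 0.0953 over all alternatives other than the estimated correlation and fry. The ranges of the lists below leave these out too. PCNA, the clamp of DNA replication, went from 10.3 ± 1.42 to 4.55 ± 0.513 FPKM. Phase I enzymes had 14 higher, 4 lower and 5 not past of 23, with 14 and 4 adjusted over the list alone (camera adjusted p = 0.0454; adjusted p = 0.603 with an estimated correlation), and 0.073, 0.0561 and 0.052 without Control replicate 1, Control replicate 2 or VD3 replicate 2 (range 0.0214 to 0.073). Lipid absorption genes had 15 higher, 4 lower and 7 not past of 26, with 15 and 4 adjusted over the list alone (camera adjusted p = 0.0454; adjusted p = 0.635 with an estimated correlation), and 0.0509 and 0.0561 without Control replicate 1 or 2 (range 0.0214 to 0.0561).

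Cholesterol synthesis genes had 15 higher, 3 lower and 7 not past of 25, and 16 and 3 adjusted over the list alone (camera adjusted p = 0.0454; adjusted p = 0.883 with an estimated correlation). INSIG1 and MSMO1 rose by 0.86 each on the log2 scale and PMVK fell by 0.94. The set call was lost without Control replicate 1 or 2, VD3 replicate 2, VPA replicate 2 or VD3VPA replicate 1 (adjusted p 0.0832, 0.0728, 0.052, 0.0504 and 0.0792, in a range of 0.0288 to 0.0832). For p53 targets, 12 rose, 2 fell and 6 did not pass of 20, with 12 and 2 adjusted over the list alone (camera adjusted p = 0.0463; adjusted p = 0.711 with an estimated correlation). That call was lost without Control replicate 1 or 2, VD3 replicate 2, VPA replicate 2 or VD3VPA replicate 2 (0.0832, 0.0561, 0.0566, 0.0539 and 0.0533), with equal FPKM sums (0.054) and with GC content and length trends removed (0.0639), in a range of 0.0402 to 0.0832. TP53INP1 went from 4.73 ± 0.466 to 19.1 ± 0.75 FPKM. The responsive genes of histone deacetylase inhibitors had 11 higher, 4 lower and 5 not past of 20, with 12 and 4 adjusted over the list alone (camera adjusted p = 0.0568).

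**Figure D2:**
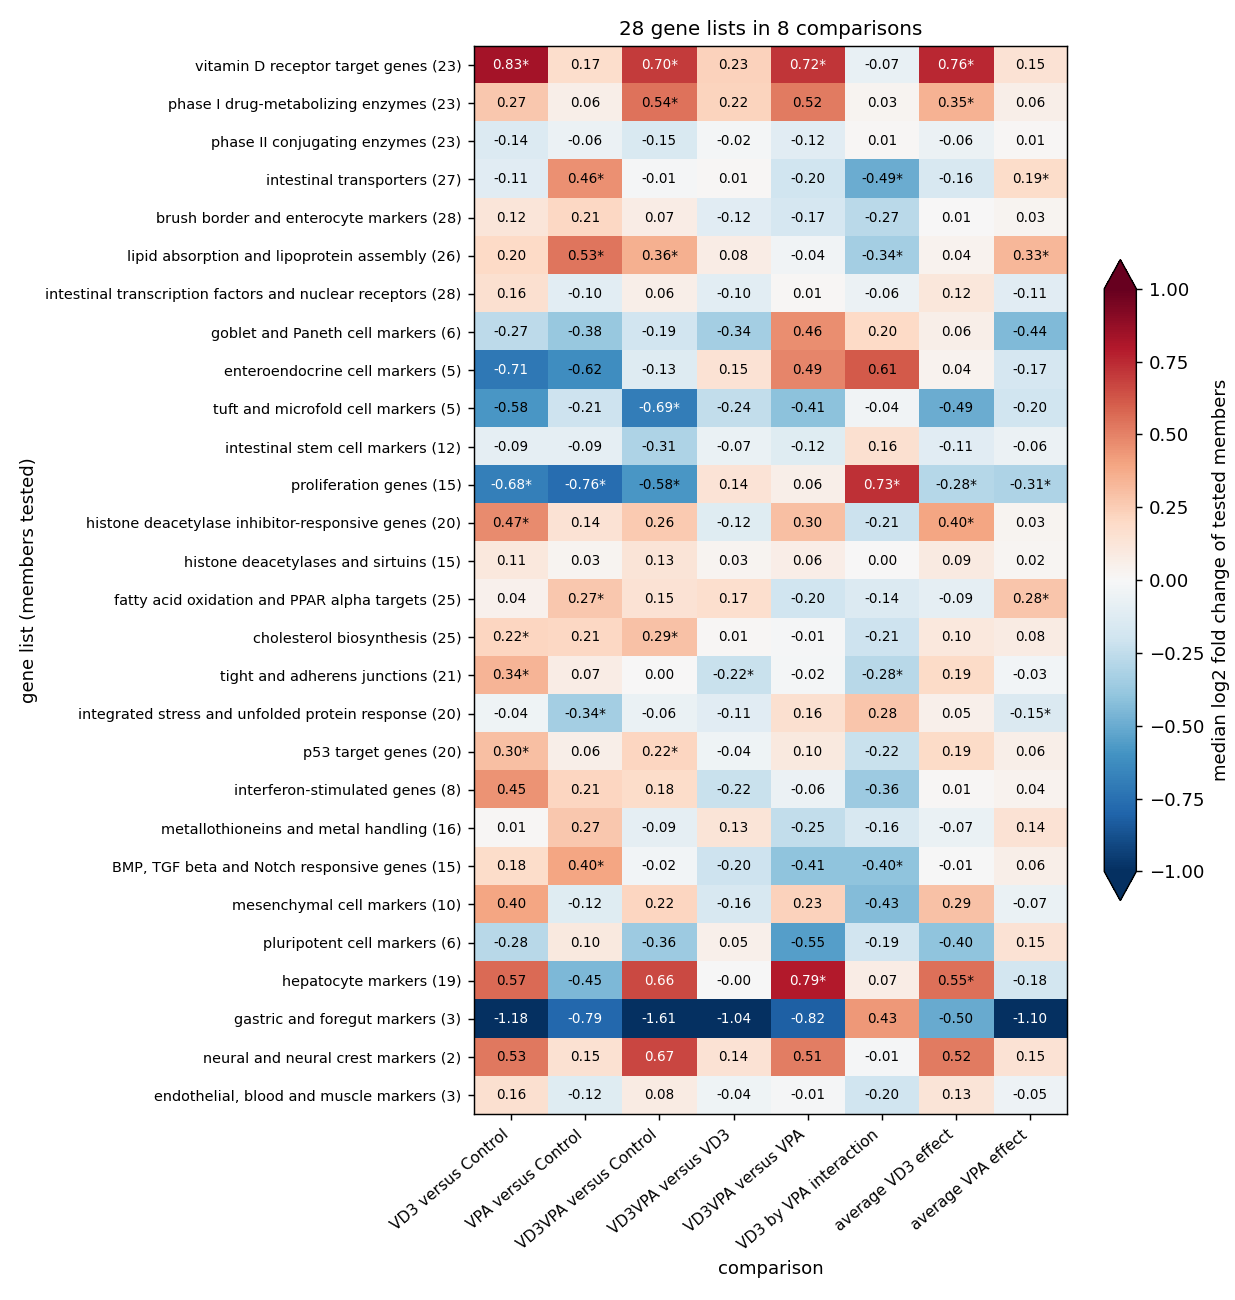
Median log2 fold change of the tested members of 28 gene lists (vertical axis, number tested in brackets) in 8 comparisons (horizontal axis), from log2(FPKM + 1) values. An asterisk marks a camera adjusted p under 0.05 with the preset correlation. Vitamin D receptor targets passed in the 3 comparisons that add VD3 and in the average VD3 effect.

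Adding VPA to VD3, in the comparison of VD3VPA with VD3, moved fewer genes. PRG4 rose from 1.95 ± 0.216 to 28.3 ± 4.03 FPKM and the water channel AQP1 from 19.6 ± 2.31 to 68.9 ± 2.12. CYP3A4 rose 2.61-fold, from 23.6 ± 1.72 to 61.5 ± 3.27 FPKM, and FABP2, the intestinal fatty acid-binding protein, 2.26-fold, from 22.6 ± 3.88 to 51.1 ± 9.66. METTL7A, WFDC2 and CDC42EP5 rose by 2.02, 1.77 and 1.63 on the log2 scale. C6orf15 fell from 64.5 ± 7.79 to 10.3 ± 0.588 FPKM, and the acute-phase protein gene SAA1 from 8.68 ± 1.67 to 1.70 ± 0.25. UGT2B15 (uncertain as above), CTSE and GPRC5A fell by 1.54, 1.42 and 1.42 on the log2 scale.

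In this comparison 2200 genes rose, 2159 fell and 8202 did not pass an adjusted p of 0.05 (limma with Benjamini-Hochberg adjustment). Of those called, 117 changed at least 2-fold, 67 higher and 50 lower. The share of higher genes among the calls was 50.5%, but 60.1% with libraries scaled to their own totals, so this balance depends on the scaling. The adjusted p was 3.42e-09 for PRG4 (3.31, SE 0.087), 3.34e-07 for CYP3A4 (1.35, SE 0.060) and 1.16e-07 for C6orf15 (-2.53, SE 0.097). Tight and adherens junction genes fell as a group, with 2 higher, 12 lower and 7 not past of 21, and 2 and 13 adjusted over the list alone (camera adjusted p = 0.00154; adjusted p = 0.754 with an estimated correlation). CLDN6, EPCAM and F11R fell by 0.53, 0.43 and 0.32 on the log2 scale.

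Adding VD3 to VPA, in the comparison of VD3VPA with VPA, raised these named targets: CYP24A1 1602-fold, S100G 391-fold, CYP3A4 435-fold, CP 180-fold and PRODH2 239-fold. The baseline of these ratios is a low level in the VPA libraries that varied between them, such as 5.29 ± 7.60 FPKM for S100G. Without VPA replicate 1 the ratios of S100G, CP and PRODH2 were 2282, 405 and 499. The neutral amino acid carrier SLC43A2 fell from 15.3 ± 1.48 to 0.587 ± 0.0215 FPKM and ENC1 from 135 ± 7.58 to 12.4 ± 1.09. SUSD2 and BTNL3 fell 9.12-fold and 9.04-fold, and PTH1R, uncertain as above, by 3.50 on the log2 scale.

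Here 3590 genes rose, 4358 fell and 4613 did not pass an adjusted p of 0.05 (limma with Benjamini-Hochberg adjustment), and 971 changed at least 2-fold, 510 higher and 461 lower. The share of higher genes among the calls was 45.2%, but 55% with libraries scaled to their own totals, so the excess of falls depends on the scaling. The adjusted p was 1.13e-13 for CYP3A4 (5.78, SE 0.060) and 2.97e-10 for SLC43A2 (-3.36, SE 0.1). Vitamin D receptor targets had 17 higher, 4 lower and 2 not past of 23, with 17 and 4 adjusted over the list alone (camera adjusted p = 9.98e-06; adjusted p = 0.529 with an estimated correlation). Hepatocyte markers rose, with 13 higher, 3 lower and 3 not past of 19, and 14 and 3 adjusted over the list alone (camera adjusted p = 0.0189; adjusted p = 0.839 with an estimated correlation). FGG went from 56.9 ± 17.2 to 1149 ± 120 FPKM, FGB from 265 ± 61.6 to 2765 ± 224 and FGA from 105 ± 28.9 to 1259 ± 144.

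Across genes, the effects of VD3 with and without VPA correlated more closely than those of VPA with and without VD3. The log2 fold changes for VD3 without and with VPA correlated across the 12561 genes at r = 0.720 (Spearman rho 0.605), and 4902 genes were called in the same direction in both. Of these 2341 were higher and 2561 lower, where independent lists would share 1123 and 1361, and 741 were called in opposite directions. For VPA without and with VD3 the correlation was r = 0.202 (rho 0.137), with 1605 genes in the same direction, 1001 higher and 604 lower against 651 and 498 for independent lists, and 988 in opposite directions. The 2 comparisons of each pair share no libraries, and genes are not independent replicates. Of the opposite calls for VPA, 668 rose with VPA alone and fell when VPA was added to VD3, where independent lists would give 639, and 320 fell with VPA alone and rose when it was added to VD3, where they would give 508.

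**Figure D3:**
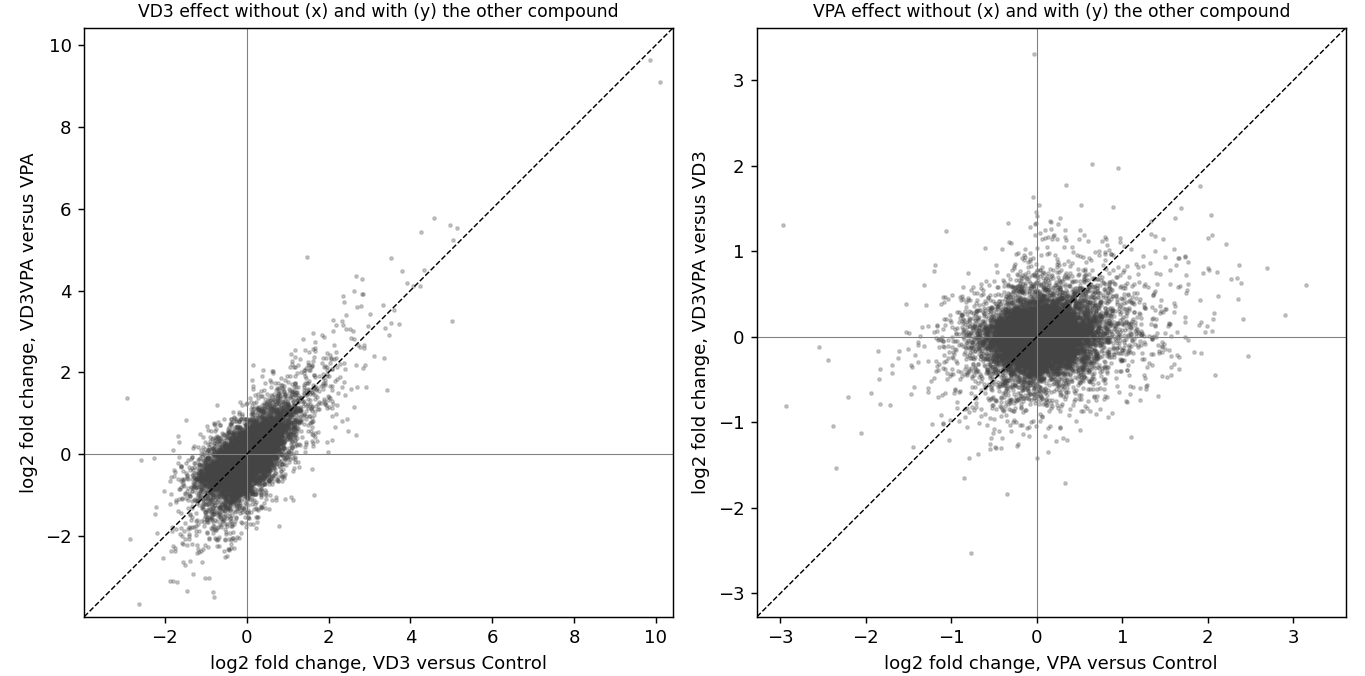
Log2 fold changes of the 12561 tested genes (points) for VD3 (left) and VPA (right), without the other compound on the horizontal axis and with it on the vertical axis; the dashed line marks equal effects. The VD3 effects correlate at r = 0.720 and the VPA effects at r = 0.202.

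The interaction tested, gene by gene, whether the effect of a compound differed when the other was present. HSD3B1, ALPL and PTH1R (uncertain as above) rose with VPA alone. With both compounds they were lower than the sum of the separate effects by 2.55, 2.65 and 2.70 on the log2 scale. HSD3B1 stood at 8.15 ± 0.864 FPKM with both compounds against 29.8 ± 0.882 with VPA alone. SLC43A2 and the complement gene C3 had interactions of -2.53 and -2.27. C3 stood at 3.52 ± 0.194 FPKM in Control, 9.11 ± 1.94 with VD3, 8.74 ± 0.971 with VPA and 3.45 ± 0.151 with both. PRG4 had an interaction of 3.34, NPW 2.43, SLC6A11 2.30 and AKR1B10 2.17. NPW and AKR1B10 fell to about the same level with VD3, VPA and both, at 1.26 ± 0.548, 1.28 ± 0.282 and 1.06 ± 0.243 FPKM for NPW.

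The interaction passed an adjusted p of 0.05 for 5566 genes (limma with Benjamini-Hochberg adjustment), 2390 positive and 3176 negative, with 462 of at least 1 log2 unit, 154 positive and 308 negative. The adjusted p was 2.11e-06 for HSD3B1 (SE 0.16) and ALPL (SE 0.168) and 1.23e-07 for PRG4 (SE 0.122). The share of positive calls was 42.9%, but 55.9% with libraries scaled to equal FPKM sums and 67.3% scaled to their own totals. Scaling to own totals moved the median interaction of all genes from -0.01 to 0.11. The interaction of CYP3A4 depended on the setting: it was 1.2 (adjusted p = 3.54e-06), 0.49 with a pseudocount of 0.1 (adjusted p = 0.118) and -0.90 with voom on recovered fragments (adjusted p = 0.257), in a range of 4.12e-07 to 0.257 over all alternatives. On the ratio scale CYP3A4 was 2.61-fold higher with VD3VPA than with VD3. For VPA against Control, which did not pass (adjusted p = 0.0547), the ratio rests on 45 against 10 fragments, with a 95% counting interval of 2.72 to 12.2. BOLA2B, with 1379, 1926 and 64 fragments in the Control libraries, had an interaction of 4.28 (adjusted p = 0.0462) that is uncertain and lost its call without any library other than Control replicate 3 or VD3VPA replicate 1 or 2 (0.0705 to 0.103).

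Proliferation genes had positive interactions, 13 of 15 with 0 negative and 2 not past, and 13 adjusted over the list alone (camera adjusted p = 1.31e-07; adjusted p = 0.249 with an estimated correlation). MCM7 stood at 5.73 ± 0.479, 2.76 ± 0.109, 2.19 ± 0.125 and 3.14 ± 0.180 FPKM in Control, VD3, VPA and VD3VPA. Intestinal transporters had 3 positive, 15 negative and 9 not past of 27, with 3 and 15 adjusted over the list alone (camera adjusted p = 0.00108; adjusted p = 0.21 with an estimated correlation). The efflux pump ABCG2 stood at 74.5 ± 5.11, 123 ± 13.2, 181 ± 13.9 and 87.2 ± 2.16 FPKM in the same order, and SLC40A1 at 32.2 ± 2.22, 14.8 ± 0.680, 68.2 ± 4.15 and 12.9 ± 0.685. Lipid absorption genes had 4 positive, 15 negative and 7 not past of 26, with 4 and 15 adjusted over the list alone (camera adjusted p = 0.00546; adjusted p = 0.601 with an estimated correlation). APOB stood at 437 ± 17.4, 477 ± 16.9, 877 ± 44.3 and 429 ± 11.2 FPKM. BMP, TGF beta and Notch responsive genes had 1 positive, 10 negative and 4 not past of 15, and 1 and 12 adjusted over the list alone (camera adjusted p = 0.00154; adjusted p = 0.324 with an estimated correlation). Junction genes had 1 positive, 12 negative and 8 not past of 21, with 1 and 12 adjusted over the list alone (camera adjusted p = 0.00391; adjusted p = 0.605 with an estimated correlation).

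Averaged over both levels of VPA, VD3 raised CYP24A1, S100G, CP, CYP3A4 and TRPV6 by 9.74, 9.60, 5.33, 5.18 and 5.14 on the log2 scale and lowered the calcium-regulating hormone gene STC1, TDO2, BTNL3, SUSD2 and ENC1, which fell by 2.49, 2.47, 2.45, 2.41 and 2.40. Averaged over both levels of VD3, VPA raised HSD3B1, MYL3, PCP4L1, PDK4 and NID1 by 1.88, 1.75, 1.73, 1.65 and 1.62. UGT2B15, AGR2, TFF1, ODC1 and PSAPL1 fell by 1.94, 1.87, 1.71, 1.46 and 1.37. MYL3 and UGT2B15 are uncertain as above. The average VD3 effect passed an adjusted p of 0.05 for 8862 genes (limma with Benjamini-Hochberg adjustment), 4141 higher and 4721 lower, and the average VPA effect for 6214, 3472 higher and 2742 lower. At least 2-fold changes numbered 720 and 97. The share of higher genes for VPA was 55.9%, and 44.4% with libraries scaled to their own totals. Both averages were called in the same direction for 2579 genes and in opposite directions for 2248, with r = 0.074 across genes (rho 0.057). Independent lists would share 1145 higher and 1031 lower genes, where 1397 and 1182 were observed.

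For the average VD3 effect, vitamin D receptor targets had 18 higher and 2 lower of 23 (20 adjusted over the list alone; camera adjusted p = 2.11e-06; adjusted p = 0.412 with an estimated correlation). Genes responsive to histone deacetylase inhibitors had 13 higher and 3 lower of 20 (16 adjusted over the list alone; camera adjusted p = 0.00478; adjusted p = 0.531 with an estimated correlation). For the average VPA effect, lipid absorption genes had 18 higher and 0 lower of 26 (18 adjusted over the list alone; camera adjusted p = 2.98e-05; adjusted p = 0.404 with an estimated correlation). Intestinal transporters had 13 higher and 3 lower of 27 (17 adjusted over the list alone; camera adjusted p = 0.0155; adjusted p = 0.404 with an estimated correlation). Fatty acid oxidation genes had 18 higher and 5 lower of 25 (23 adjusted over the list alone), and integrated stress genes 2 higher and 11 lower of 20 (14 adjusted over the list alone), each with a camera adjusted p = 0.00553 (adjusted p = 0.566 with an estimated correlation). PDK4 and the transcription factor CREB3L3 rose by 1.65 and 1.40 on the log2 scale, and PSAT1 fell by 0.55.

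A set of 14 genes chosen before the data were examined was followed in every group. FABP2 stood at 2.64 ± 0.545, 22.6 ± 3.88, 3.31 ± 0.874 and 51.1 ± 9.66 FPKM in Control, VD3, VPA and VD3VPA, and its rises with VD3 (2.69, adjusted p = 2.03e-07) and VD3VPA (3.83, adjusted p = 8.94e-09) passed. The peptide carrier SLC15A1 stood at 57.8 ± 3.87, 79.9 ± 8.65, 97.1 ± 12.7 and 52.3 ± 0.753 FPKM, higher than Control with VD3 (adjusted p = 0.00118) and VPA (adjusted p = 5.69e-05) and not past with both (adjusted p = 0.216). Its interaction was -1.33 (adjusted p = 2.28e-05). Sucrase-isomaltase (SI), a disaccharidase of the brush border, was at 1.15 ± 0.0839 FPKM in Control and fell to 0.231 ± 0.0830, 0.114 ± 0.0260 and 0.105 ± 0.0328, with adjusted p of 2.93e-06, 1.79e-06 and 5.69e-07. The microvillus protein villin (VIL1) was at 132 ± 3.53, 110 ± 3.44, 141 ± 6.01 and 99.8 ± 2.10 FPKM, lower than Control with VD3 (adjusted p = 0.000251) and VD3VPA (adjusted p = 8.61e-06). The intestinal transcription factor CDX2 was at 49.6 ± 6.07, 54.7 ± 1.21, 44.3 ± 2.37 and 50.9 ± 2.13 FPKM, and none of its 3 comparisons with Control passed (lowest adjusted p = 0.0998, limma; without Control replicate 1 the VPA value was 0.0409, and without Control replicate 3 those of VD3 and VD3VPA were 0.00275 and 0.0448; the VPA value ranged from 0.00715 to 0.401 over all alternatives).

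The vitamin D receptor gene VDR (chromosome 12, 47841537 to 47943048) was at 3.21 ± 0.218, 2.87 ± 0.0607, 2.97 ± 0.808 and 3.43 ± 0.0869 FPKM and passed in no comparison with Control (adjusted p = 0.346, 0.444 and 0.573). Without VPA replicate 1 it was lower with VPA than in Control (-0.26, adjusted p = 0.00461) and had an interaction of 0.46 (adjusted p = 0.00141). The efflux pump ABCB1 was at 1.54 ± 0.171, 2.01 ± 0.295, 2.13 ± 0.127 and 2.62 ± 0.174 FPKM and rose with VPA (0.30, adjusted p = 0.00642) and VD3VPA (0.51, adjusted p = 0.00012). With VD3 its adjusted p was 0.017, and 0.0652, 0.0522 and 0.0743 (range 0.00283 to 0.0743 over all alternatives) without Control replicate 2, VD3 replicate 1 or VD3 replicate 2. The cell cycle inhibitor CDKN1A was at 156 ± 0.880, 178 ± 8.91, 214 ± 14 and 150 ± 5.38 FPKM, and H1F0 at 102 ± 6.39, 153 ± 4.53, 148 ± 2.78 and 137 ± 4.91. CDKN1A rose with VPA (0.46, adjusted p = 3.78e-05) and had an interaction of -0.70 (adjusted p = 4.24e-05), and H1F0 rose in all 3 groups (0.57, 0.53 and 0.42) with an interaction of -0.69 (adjusted p = 3.03e-05). LGR5, a stem cell marker, stood at 0.151 ± 0.0228, 0.117 ± 0.0417, 0.240 ± 0.0631 and 0.0395 ± 0.00968 FPKM, and the proliferation marker MKI67 at 0.497 ± 0.0921, 0.0647 ± 0.0276, 0.146 ± 0.0272 and 0.170 ± 0.0464. Both lay under the filter on low values and were not tested.

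**Figure D4:**
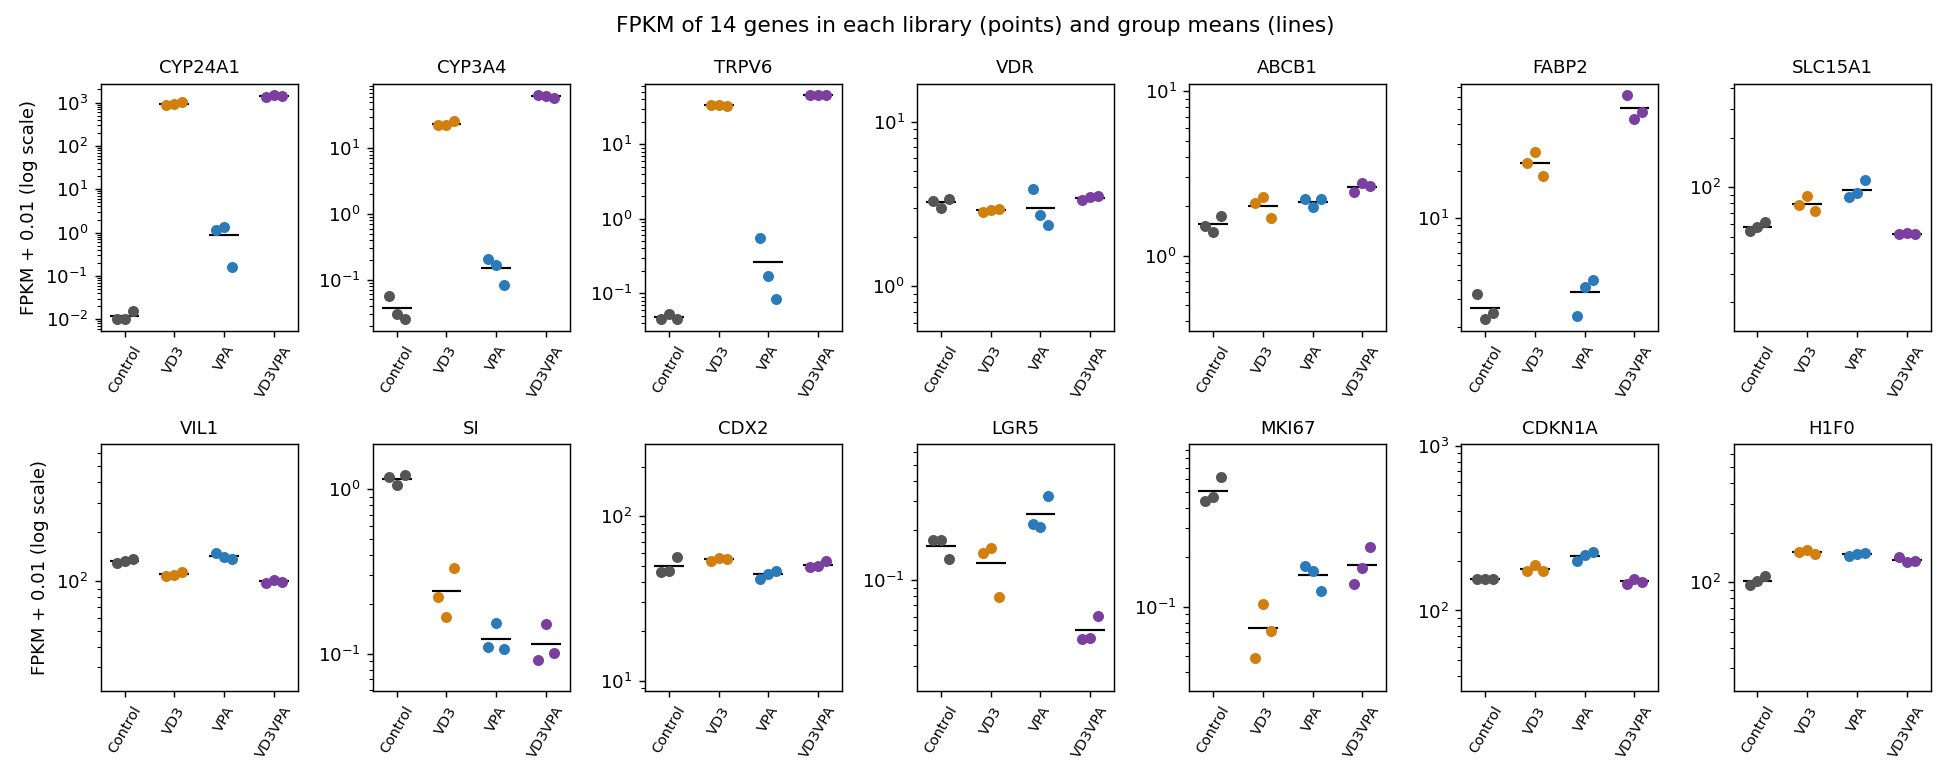
FPKM + 0.01 on a log axis for 14 genes chosen in advance, in the libraries of Control, VD3, VPA and VD3VPA (points, 3 per group) with group means (lines); each panel has its own axis range. CYP24A1, CYP3A4 and TRPV6 lie far higher in every library with VD3 than in any without it, and VDR does not.

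In the VPA libraries, some VD3-induced genes lay above their Control level. CYP24A1 had 351 fragments in the VPA libraries together against 1 in Control, a ratio of 428 with a 95% counting interval of 76.2 to 16900, and 0.891 ± 0.649 FPKM (adjusted p = 0.00441 by limma, log2 fold change 0.85, SE 0.203). CYP3A4 had 45 fragments against 10 (adjusted p = 0.0547; 0.0335 without VD3 replicate 3 and 0.027 without VPA replicate 3). TRPV6 had 317 fragments against 56, of which 228 were in VPA replicate 1, and an adjusted p of 0.0453, which exceeded 0.05 without any library other than VPA replicate 2 or 3 (0.0571 to 0.0898). S100G had 255 fragments against 21, of which 228 were in VPA replicate 1. For VD3VPA against VD3, the rises of CYP24A1 (0.62, adjusted p = 0.0342) and TRPV6 (0.46, adjusted p = 0.0044) lost their call with a pseudocount of 0.1, at 0.362 and 0.314. That of CYP24A1 was also lost without VD3 replicate 1 or 2 or VD3VPA replicate 1, 2 or 3 (0.0985, 0.0814, 0.0594, 0.0941 and 0.0812). Counting intervals cover counting error only.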

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

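The splits of the libraries were planned, and the tests of scaling, GC content and gene length were chosen after the interaction had been seen. Each result of this part was singled out because the effect of a compound differed between cultures with and without the other, by the interaction test. That test passed for 5566 genes. Among the named genes it was 4.28 for BOLA2B (uncertain, see the report), 3.34 for PRG4, 2.43 for NPW, 2.3 for SLC6A11 and 2.17 for AKR1B10. The lowest were -2.7 for PTH1R (also uncertain), -2.65 for ALPL, -2.55 for HSD3B1, -2.53 for SLC43A2 and -2.27 for C3. Of the genes chosen in advance, CYP3A4 had 1.2, VIL1 -0.23, SI 0.79, CDKN1A -0.7, H1F0 -0.69, FABP2 0.91 and SLC15A1 -1.33. SI fell by 0.80 with VD3, 0.95 with VPA and 0.96 with both. The falls with VD3 and VPA together exceed what log2(FPKM + 1) can lose from its low Control level. On this scale the positive interaction of SI was therefore fixed, and its value there does not show an effect of 1 compound on the other. Its call held under every alternative that tested it. Among these was voom on recovered fragments, so the call did not rest on the pseudocount of 1 FPKM alone. At these low levels it is not read further. The interaction of CYP3A4 depended on the pseudocount. VIL1 lost its call with equal FPKM sums (adjusted p = 0.115), quantile normalization (0.569), own totals (0.391) and GC content and length trends removed (0.0576), over a range of 0.0106 to 0.569. By list, the median interaction was -0.49 for intestinal transporters, -0.34 for lipid absorption and lipoprotein assembly, 0.73 for proliferation genes, -0.28 for tight and adherens junctions and -0.4 for BMP, TGF beta and Notch responsive genes. With an estimated correlation none of the 5 passed, at an adjusted p of 0.21, 0.601, 0.249, 0.605 and 0.324.

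Many genes responded to VPA in one way without VD3 and in another with it, and technical causes were weighed against the design's own one, that the compounds act on each other. Trends on GC content and gene length as the whole cause are excluded: 5102 of the 5566 calls kept sign and threshold with the trends removed. The scaling of the libraries is excluded as the whole cause too, since at least 4388 of the calls did so under each of 3 other scalings, although the balance of positive and negative calls moved with it. An unrecorded batch that follows the 4 groups cannot be told apart from the compounds, because the labels give none. A share of the interaction may also come from the log scale where effects of both compounds saturate. NPW and SI, for example, fell to low levels with either compound and little further with both. Whether a floor was reached was not tested. Such saturation was not tested across genes beyond the pseudocount (CYP3A4 0.49 with 0.1).

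For the interaction, 1 of 100 random assignments of the libraries to 4 groups gave as many calls, the real one with 5566, and the highest other gave 2433. For the average VD3 effect this was 1 of 100 (8862, highest other 3650), and for the average VPA effect 1 of 100 (6214, highest other 5566, which is the split that forms the interaction). For each pair of groups the splits were too few for a share under 0.05. The real value and the highest other were 7852 and 0 for VD3, 6614 and 0 for VPA and 8072 and 1 for VD3VPA against Control. They were 4359 and 0 for VD3VPA against VD3 and 7948 and 0 for VD3VPA against VPA, with the real split 1 of 10 in each. The real assignment was always among those counted, so 1 is the lowest count possible. The other assignments put effects of the compounds into the spread within groups, which lowers their calls. Those for the interaction thus test for any group effect and do not weigh the interaction itself.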

How the results depend on the processing

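Alternatives chosen after seeing the data were voom on recovered fragments, own library totals, GC content and length trends removed (with and without the replicate block), lists under other scalings and the agreement under median-of-ratios; the others were planned. With a filter of FPKM 5, where 6717 genes were tested, the counts were 4785 for VD3, 4183 for VPA, 4883 for VD3VPA against Control, 2877 against VD3, 4825 against VPA, 3647 for the interaction, 5252 and 3851 for the average VD3 and VPA effects, 3112 for the agreement of VD3 effects and 1704 for the overlap of the averages; fewer genes tested explain this. With the 2-fold threshold added they were 804, 363, 956, 117, 971, 462, 720 and 97 in the same order, by its construction. Of 200 list results 37 were called; an estimated correlation called 0 and fry 137. Voom on recovered fragments adds no pseudocount of 1 FPKM. With it the interaction of CYP3A4 turned to -0.90 (adjusted p = 0.257) and that of TRPV6 to -1.81 (adjusted p = 0.0363). For VPA against Control, the main fit gave log2 changes of 0.15 and 0.26, where mean FPKM rose 5.16-fold and 6.82-fold. Without VPA replicate 1 that of TRPV6 rose 3.09-fold. Adding VPA to VD3 gave 1.35 and 0.46 in the main fit. The positive interactions of both genes thus depend on the pseudocount, while the ratios rest on few fragments.

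Over single left-out libraries, each leaving groups of at least 2, the counts ranged from 7118 to 7760 for VD3, 5875 to 6582 for VPA, 7309 to 8049 for VD3VPA against Control, 3316 to 4708 against VD3, 7146 to 8110 against VPA, 4823 to 5374 for the interaction, 8395 to 8651 and 5574 to 6132 for the averages, 4473 to 4713 and 1259 to 1722 for the agreement of VD3 and VPA effects, 2231 to 2539 for the overlap and 29 to 42 for the lists. The replicate block gave 7764, 6544, 8022, 4233, 7881, 5447, 8786 and 6135 genes, 4857, 1591 and 2526 for agreement and overlap, and 36 lists. Same-numbered libraries correlated at -0.083 to 0.152 (3 of 18 pairs over 0.1) and 5 of 12 libraries were closest to their own number, so the numbers do not pair the libraries.

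Of 168 calls of named or fixed genes, 151 held under every alternative that tested them, 144 of these tested without each of the 12 libraries, while 12 were lost without a single library and 17 under another setting. Of 37 list calls 0 held with an estimated correlation, and fry was compared by its total of calls only. With these alternatives set aside, 27 held where tested (26 of them without each of the 12 libraries). Of the 37, 10 were lost without a single library and 4 under another setting. Not tested were the 6 calls of SI without a Control library, that of WFDC2 for VD3VPA against VD3 without a VD3VPA library, that of tuft and microfold cell markers without a Control library or VPA replicate 2, and 16 gene calls with the filter of FPKM 5. The 53 gene calls of the interaction and the averages have no fit of only the groups compared. Lists were run under a pseudocount of 0.1, the other scalings, the replicate block, trends removed, fry, the estimated correlation and left-out libraries only. Among 27 gene results and 163 list results not called, 13 and 11 were gained without a single library. Among the list calls lost this way were phase I enzymes, proliferation genes and hepatocyte markers for the average VD3 effect and proliferation genes for the average VPA effect, left undescribed above. Genes at low levels are limited by depth and by the pseudocount, and LGR5 and MKI67 were not tested. The planned test on deposited counts was not run, and median-of-ratios scaling moved almost nothing since the deposited values already carry it.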

Other observations

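The tests of carry-over and of mitochondrial RNA in this part were all chosen after their results had been seen. AFP, a gene of fetal liver and yolk sac chosen after its values were seen, stood at 26953 ± 409 FPKM in Control, 22931 ± 946 with VD3, 30636 ± 1670 with VPA and 22799 ± 1598 with VD3VPA. ALB of hepatocytes, chosen likewise, stood at 1499.6 ± 70.4, 1354 ± 313, 509 ± 163 and 1189.7 ± 101 FPKM in the same order. These levels do not show which cells of the cultures held the RNA. The 10 most abundant genes held 17.4% to 21.3% of the fragments of a library.

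The libraries with VPA alone held some transcripts that VD3 induces above their Control level. Of 8 genes at least 100-fold higher with VD3 and with at least 1000 fragments there, CYP24A1, S100G, TRPV6 and CP had 351, 255, 317 and 253 fragments in the VPA libraries against 1, 21, 56 and 30 in Control. PRODH2 had 60 against 43, of which 42 were in VPA replicate 1, against 8, 20 and 15 in the Control libraries. PKNOX2 had 2 against 4 and TREM1 1 against 0, so these stood near the Control level, and CYP3A4 had 45 against 10. In percent of the VD3 level, S100G, CP, TRPV6 and PRODH2 stood at 0.345%, 0.942%, 0.771% and 1.02%. Without VPA replicate 1 they stood at 0.0591%, 0.418%, 0.349% and 0.486%.

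Carry-over of RNA or fragments from libraries that received VD3 would bring all 8 genes in the proportions of a mixture of these libraries. The interval around the best mixture was widened to the largest spread between replicate libraries, a chi-square per gene of 17. In VPA replicate 1, 4 of 8 genes lay outside it, where more than 2 were needed: CYP24A1 had 165 fragments against 522 expected, S100G 228 against 105, CP 183 against 49.1 and TRPV6 228 against 77.3. Carry-over from the 6 libraries that received VD3 is thus excluded as the whole cause in VPA replicate 1. The test does not cover other sources of VD3-induced RNA. In VPA replicates 2 and 3 the count was 0 of 8 each, and with so few fragments carry-over cannot be told apart from an effect of VPA there. An effect of VPA on these genes remains a hypothesis.

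This test replaced earlier ones, which set the libraries against counting error alone and had 5, 4 and 2 of 8 genes outside in VPA replicates 1, 2 and 3. The earliest, which by its own bound had left carry-over open, used the ratio of S100G to CYP24A1 fragments in each VPA library, 1.38 (1.13 to 1.7), 0.0848 (0.0454 to 0.146) and 0.619 (0.285 to 1.3), against 0.143 to 0.197 in the libraries with VD3.

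Mitochondrially encoded mRNAs were lower with VD3 for 10 of 13 and higher for 1, MT-ATP8. With own library totals 12 were lower and 0 higher. MT-CO1 went from 8268 ± 261 to 5024 ± 87.2 FPKM. A lower yield of all mitochondrial RNA is excluded as the whole cause, since it lets none rise, and 7 of 29 mitochondrial RNAs of at least 5 FPKM rose with VD3 (6 with own library totals, the fewest over 4 scalings). Among them the ribosomal RNA MT-RNR2 rose by 0.83 on the log2 scale, from 2181 ± 9.65 to 3872 ± 158. Less efficient poly-A selection with VD3 cannot be told apart from an effect of VD3: 8 nuclear RNAs without a poly-A tail had a median of -0.29 with an SD of 0.69 across them, where the bound was 0.414. That spread was taken after the value was seen, in place of a bootstrap SE of 0.256 that would have excluded the explanation.

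With VPA 11 of the 13 mRNAs were lower and 0 higher, with MT-ND3 at 5162 ± 268 FPKM in Control and 2691 ± 206. Quantile normalization gave 8 lower and 1 higher. By the same count, 5 of the 29 mitochondrial RNAs were higher with VPA (3 with own library totals, the fewest over 4 scalings). No mRNA and neither ribosomal RNA rose in the deposited scaling, so those that rose were transfer RNAs. The count was chosen after its values were seen and does not exclude a lower yield of the mRNAs and ribosomal RNAs. The 21 transfer RNAs tested had a median of 0.33 on the log2 scale with an SD of 0.42 across them, against -0.47 for the 13 mRNAs, while the ribosomal RNAs MT-RNR1 and MT-RNR2 were lower, at -0.43 and -0.22. The count replaced earlier tests, the rise of a single RNA for VD3 and for VPA, and before that a test for VPA which by its own bound had left the explanation open: 6 of the 13 mRNAs differed from their median by more than 3 standard errors, and more than 6 were needed. A lower yield as a share of the cause, and poly-A selection with VPA, were not tested, so the cause stays open.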
